A study of Mus musculus with 12 samples.

How the data were processed

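RNA of 12 mouse cultures was measured on Affymetrix arrays with 45101 probe sets. Per the labels, total RNA was extracted with Trizol, the iPS line was 38C2 and the ES line EB3, and the neurospheres were grown in a medium named MHM. The deposited values are signal intensities on a linear scale, made with MAS5 (version not given) and Affymetrix Expression Console 1.1, per the submitters' processing notes. The 2%-trimmed mean of the deposited values was 100 on each array. Each array scaled in this way hides a change in the total amount of RNA, and MAS5 signals of dim probe sets are noisy. Detection calls were not used here, and the depth of an array has no count behind it.

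The samples were grouped by the labels into 7 groups of 1 or 2 arrays. The labels do not say that arrays of a group came from repeat cultures. They differ in line (iPS or ES) or in medium, so the p-values measure only the spread between these arrays. All 12 columns were matched to samples by their names. Probe sets were named through the platform's annotation as GEO holds it. Of the probe sets other than the 64 Affymetrix controls, 34945 had 1 symbol, 932 had several and 9160 had none. Symbols were set against a gene table of the assembly GRCm38.p6, which changed 0 of them, and no coordinates were used.

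From the deposited intensity, log2(signal + 5) was computed, 5 being 0.05 times the trimmed mean. A probe set entered the tests if it reached 20, or 0.2 times the trimmed mean, on at least 1 array. A gene was represented by the passing probe set naming only that gene with the highest mean over all arrays, which left 13638 genes, 6395 of them with several passing probe sets. Of the called named genes whose other probe sets passed, 29 of 29 had the same sign on all of them for the comparison with adult fibroblasts, 31 of 34 with GE neurospheres (not Csf1r, Laptm5 and Mbp), 25 of 27 with pluripotent cells (not Klk1, nor Mycn, which was called in the opposite direction) and 39 of 40 with secondary neurospheres (not Laptm5). The sign also differed for Ncam1 between primary neurospheres and pluripotent cells and for Mbp between secondary and primary neurospheres. Named genes that were not called disagreed too. These were Gfap and Klf4 against the adult fibroblasts (Klf4 at -1.10 and, on its other probe set, 1.43), Gfap against the pluripotent cells, and Col1a1 and Col1a2 against the secondary neurospheres. In the other comparisons they were Col1a1, Col1a2 and Gfap for primary against pluripotent, Fbln2 and Gfap for secondary against primary, Gfap and Mbp for adult against embryonic, and Klf4, Pax6 and Xist for iPS against ES origin.

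Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, in 1 fit of all 12 arrays with 5 residual and 3.63 prior degrees of freedom. Calls had a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The 4 fibroblast-derived arrays entered as the equal mean of the adult and embryonic pairs. Groups with 1 array were assumed to vary like those with 2. Origin from iPS or ES cells was tested on 6 arrays with the stage as a term (2 residual and 4.11 prior degrees of freedom). The 24 gene lists held 480 genes, of which 412 were tested. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Media were compared without a test, with each list's median as a percentile of 10000 random lists of the same size matched on mean level.

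Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Per tested comparison the rule took the 8 highest and 8 lowest called genes without overlap between the arrays, the 4 members with the smallest adjusted p of each list called by camera and of the pluripotency, neural stem cell and fibroblast lists, and a fixed set of 12 marker genes. For media it took the 5 highest and 5 lowest genes among those at 100 or more on 1 of the 2 arrays, and the LIF, cAMP and EGF response genes that differed by 1 or more. The text names part of these.

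The replicate numbers pair the arrays of iPS and ES origin, since the same number marks the same line. The deviations from the group means correlated at 0.252 between pluripotent cells and primary neurospheres, 0.0583 between pluripotent cells and secondary neurospheres and 0.426 between primary and secondary neurospheres. Alternatives were quantile normalization, a common median, pseudocounts of 0.01 and 0.2 times the trimmed mean, no filter and a filter at the trimmed mean, the mean of probe sets, every probe set on its own, eBayes without a trend, the origin as a block, a fit of only the groups compared, and leaving out each array. Alternatives chosen after seeing the data were the adult-derived arrays alone in 3 comparisons and, for gene lists, other scalings and left-out arrays. On simulated data with 200 of 13638 genes changed, between 4.59% and 9.15% of the calls were false over the 8 comparisons, and between 46.3% and 83.6% of the genes changed by 2 on the log2 scale were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.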

Results

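Transcript levels were measured with Affymetrix microarrays in RNA from 12 mouse cultures that fall into 7 groups. Neurospheres are free-floating spheres of neural stem and progenitor cells, and the neural reference was 1 array of neurospheres from the ganglionic eminence (GE), a germinal zone of the ventral forebrain, at embryonic day 14. Adult skin fibroblasts were on 1 array. The pluripotent group held 1 array of induced pluripotent stem (iPS) cells and 1 array of embryonic stem (ES) cells, and each of these lines also gave 1 array of primary and 1 array of secondary neurospheres. Fibroblast-derived neurospheres, for which the series title names direct induction, were on 4 arrays. In the adult fibroblast-derived pair, replicate 1 was grown with EGF and cAMP and replicate 2 with leukaemia inhibitory factor (LIF), a cytokine that acts through STAT3. In the embryonic fibroblast-derived pair, replicate 3 was grown with LIF and replicate 4 with LIF and cAMP. The labels do not say how the fibroblasts were converted and name no transgene. Values are deposited MAS5 signals, scaled to a trimmed mean of 100 on each array. Between 40.4% and 49.0% of the probe sets on an array reached a signal of 20. The ratio of 3′ to 5′ control probe sets lay between 1.25 and 1.52 for Actb and between 0.709 and 0.897 for Gapdh. The precision is limited by the number of arrays: no group held more than 2. Differences are on the scale of log2(signal + 5), which understates the change of dim genes, and stand with their standard error (SE). Signals are means with the SD over arrays, and lone arrays have no SD. In every called gene that is named, the arrays of the sides compared did not overlap.

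The fibroblast-derived neurospheres were first set against each other group over 13638 genes. Averaged over arrays, they correlated best with the pluripotent cells, with a mean Pearson r across genes of 0.841 ± 0.0205 (SD over 8 pairs of arrays). The mean r was 0.794 ± 0.00956 against the adult fibroblasts (4 pairs), 0.765 ± 0.0596 against the primary neurospheres (8 pairs), 0.749 ± 0.0338 against the secondary neurospheres (8 pairs) and 0.711 ± 0.0308 against the GE neurospheres (4 pairs). Each of the 4 arrays correlated best with the iPS cells (0.856 to 0.863), but the order of these means did not hold for single arrays. The mean r was 0.809 against the ES-derived primary neurospheres, above that against the adult fibroblasts, and 0.721 against the iPS-derived ones (4 pairs each). Both adult-derived arrays correlated more with the ES-derived primary neurospheres (0.836 for replicate 1 and 0.834 for replicate 2) than with the ES cells (0.828 and 0.825) or the adult fibroblasts (0.791 and 0.809). Secondary neurospheres of iPS or ES origin correlated with the GE neurospheres at 0.886 ± 0.0105 (2 pairs), and primary ones at 0.810 ± 0.0135 (2 pairs). Average-linkage clustering on 1 - r joined the fibroblast-derived neurospheres to the pluripotent cells at a height of 0.159 and both to the adult fibroblasts at 0.243. The neurospheres of GE, iPS and ES origin formed the other branch, joined to the first at 0.262. The first 3 principal components held 39.8%, 23.5% and 11.5% of the variance. Genes are not independent replicates, so these values describe the arrays and were not tested.

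**Figure D1:**
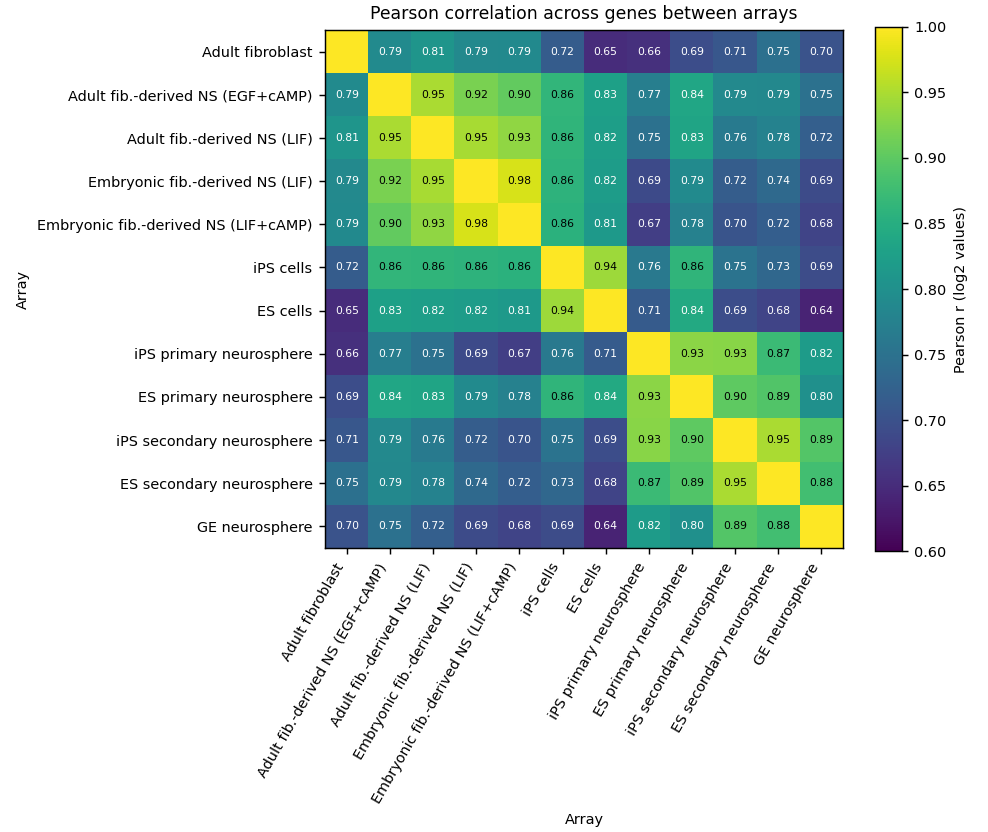
Pearson correlation across 13638 genes of log2(signal + 5) between each pair of the 12 arrays, drawn as colour from 0.6 to 1 and printed in each cell. The fibroblast-derived neurospheres (NS) lay at a mean r of 0.841 from the pluripotent cells and 0.711 from the GE neurospheres.

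The fibroblast-derived neurospheres were compared with adult skin fibroblasts, the cell type the adult pair came from. Embryonic fibroblasts were not measured. For the embryonic-derived pair, fell and rose therefore mark a difference from adult fibroblasts and not a change from its source cells. Cnn1, the smooth muscle protein calponin, fell and stood at 2.05 ± 0.968 (n = 4) against 1271 in the fibroblasts, a log2 difference of -7.51 ± 0.38 (adjusted p = 5.41e-05). Tagln fell from 4529 to 41.2 ± 27, Thy1 from 4690.0 to 57.2 ± 48.3 and Col5a1 from 3945 to 58 ± 28. Pou5f1, which encodes Oct4, rose from 1.3 to 2014 ± 180.0 (log2 difference 8.32 ± 1.85, adjusted p = 0.0144), Sall4 from 0.3 to 651 ± 248 and Tfcp2l1 from 2.2 to 438 ± 227. Sox2, a factor of both pluripotent and neural stem cells, rose from 4 to 1199 ± 930.4, and the neural progenitor genes Fabp7 and Olig2 rose to 264 ± 236 and 79.7 ± 57.4. The signal of Pou5f1, Sox2, Klf4 or Mycn was not split into endogenous and introduced transcripts.

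Of the 35 measured genes of the fibroblast list, 17 fell and 0 rose (19 adjusted over the list alone), among them Col12a1, Col1a1 at 37.4 ± 18 against 2733, and the contractile gene Tagln. Col1a2, at 980.0 ± 637 against 8334, did not pass (adjusted p = 0.201). Of 15 adhesion and epithelial-mesenchymal transition genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). The mesenchymal genes Vim and Cdh2 were among those lower, with log2 differences of -1.18 ± 0.16 and -2.35 ± 0.34, and the one higher was the epithelial cadherin Cdh1, at 970.5 ± 356 against 0.4. Cdh1 stood at 1792 and 2179 in the iPS and ES cells. Of 17 keratinocyte and epithelial genes 12 rose (14 adjusted over the list alone), with the desmosome gene Dsp at 683 ± 320.4 against 5.6 and Krt8 at 824 ± 628 against 15.8. Of 30 pluripotency genes 12 rose (21 adjusted over the list alone) and none fell. Nanog, at 961 ± 817 against 5.6, did not pass (log2 difference 5.91, adjusted p = 0.0641), and passed with the iPS or ES origin as a block (adjusted p = 0.0254). Of 29 cell cycle genes 25 rose (26 adjusted over the list alone), including the replication gene Mcm7 (2.29 ± 0.25), Top2a (1.93 ± 0.23) and the mitotic kinase Bub1 (2.81 ± 0.37). Of 24 neuronal genes 7 rose (11 adjusted over the list alone), including Stmn2 and the neurofilament gene Nefl. The mean of the neuronal list was 5.14 and 5.80 on the adult-derived and 5.24 and 5.03 on the embryonic-derived arrays. It was 3.54 in the adult fibroblasts and 5.03 and 5.17 in the iPS and ES cells. The rise therefore does not set the fibroblast-derived neurospheres apart from pluripotent cells. These 6 lists passed camera, with adjusted p = 2.86e-12 for the fibroblast, 9.97e-07 for the adhesion, 6.78e-06 for the keratinocyte and the pluripotency, 3.85e-11 for the cell cycle and 0.00662 for the neuronal list. No list call held with an estimated correlation (adjusted p = 0.0954 for the adhesion list and 0.823 for the other 5). Of 29 neural stem cell genes 12 rose and 5 fell (14 and 5 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.115, 0.0327 with a common median and 0.0317 without adult replicate 2). Nes, an intermediate filament gene of neural stem cells, stood at 127 ± 62.2 against 34.9 (adjusted p = 0.066, and 0.0307 with the block).

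The highest log2 differences included Klk1, a kallikrein of a family with near-identical members, at 4781 ± 1037 against 0.3 (9.79 ± 0.37), the chloride channel gene Ano1, L1td1 and the myelin protein gene Mal, at 1371 ± 377 against 0.1. Mycn was at 5815 ± 586 against 6.8 on its brightest probe set, beside 333 ± 143 and 35.5 ± 20.7 on the others in the fibroblast-derived neurospheres. Against the pluripotent cells the probe sets of Mycn, in this order, differed in direction, with log2 differences of 7.36, -2.49 (adjusted p = 0.0048) and -1.82 (adjusted p = 0.025). In all, 3169 genes were called with limma (adjusted p under 0.05), 2049 higher and 1120 lower. Without embryonic fibroblast-derived replicate 3 the count was 2010. With every array scaled to the same median, 47.5% of the calls were higher against 64.7% as deposited, and the median of all genes moved by -0.25 (-0.15 under quantile normalization). The fibroblasts were on 1 array, assumed to vary like the groups with 2.

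The comparison with the GE neurospheres asked how close the fibroblast-derived cells came to neurospheres from the brain. Fabp7, a radial glia fatty acid-binding protein, was lower in the fibroblast-derived neurospheres, at 264 ± 236 (n = 4) against 7197 (log2 difference -5.35 ± 0.56, adjusted p = 0.000442). The Notch target Hes5 was at 23.4 ± 28 against 1859, and the glutamate transporter Slc1a3 at 24.3 ± 7.3 against 2777. Mbp, a myelin protein, was at 41.7 ± 29.6 against 6578, and Gfap at 0.275 ± 0.15 against 514. Both were highest on the GE array, with Mbp at 964 and 299 and Gfap at 0.2 and 3 in the secondary neurospheres. Pou5f1 (2014 ± 180.0 against 0.7), Sall4 and Fbxo15 were higher. Sox2, at 1199 ± 930.4 against 3703, did not pass (adjusted p = 0.0737), nor did Nes, at 127 ± 62.2 against 133.

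Of 29 neural stem cell genes 19 were lower and 0 higher (21 adjusted over the list alone), including Sox9 (-4.35 ± 0.43), Olig2 (-3.91 ± 0.39) and Pax6 (-3.25 ± 0.46). Of 19 astrocyte genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone), including Sparcl1, and of 17 oligodendrocyte lineage genes 13 were lower and 1 higher (15 and 1), including Gpr17. The oligodendrocyte gene that was higher was Mal, at 1371 ± 377 against 55.9. The 28 cell cycle genes called of 29 were all higher (29 adjusted over the list alone), with Mcm5 at 3.98 ± 0.33 and Top2a at 2.76 ± 0.23. The cell cycle mean was 6.19 on the GE array, the lowest of all arrays, and 8.70 and 8.20 in the secondary neurospheres. The GE array also had the highest means of the oligodendrocyte (8.99) and astrocyte (10.2) lists. The shifts in these lists therefore also depend on a reference at the extreme of all arrays. Against the secondary neurospheres, 5 of 29 cell cycle genes were higher, and 10 oligodendrocyte (3 higher) and 12 astrocyte genes were lower. Of 30 pluripotency genes 18 were higher (22 adjusted over the list alone), of 17 keratinocyte genes 13 were higher, with Dsp at 6.05 ± 0.60 and Krt19 at 5.28 ± 0.64 (15 higher and 1 lower adjusted over the list alone), and of 35 fibroblast genes 14 were higher, such as Ccn2, at 1351 ± 997 against 4.4 (14 adjusted over the list alone). The LIF and STAT3 response list had 9 members higher and 1, Gfap, lower of 17 (10 and 1 adjusted over the list alone). Among the higher were Socs3, at 1593 ± 227 against 86.9, and Timp1, at 929.7 ± 127 against 25. The mean of this list was 6.94 on adult replicate 1, grown with EGF and cAMP, and 7.22 in the adult fibroblasts. It was 7.97 on adult replicate 2 and 7.83 and 8.10 on the embryonic-derived arrays, all given LIF, and 5.91 in the GE neurospheres. The fibroblast-derived array without LIF thus lay above the GE neurospheres but below those given LIF. An effect of LIF was not tested. In the EGF, FGF and MAPK response list 7 of 17 were higher (8), including Dusp6 and Ccnd1, and in the midbrain, hindbrain and spinal patterning list 9 of 29 (10), including Hoxd8. The mean of the patterning list was 5.64 and 5.16 on the adult-derived arrays and 4.49 and 4.67 on the embryonic-derived ones. It was 3.42 on the GE array and 5.54 in the adult fibroblasts, where Hoxd8 stood at 216. The shift therefore does not show a gain over adult fibroblasts. Endothelial and pericyte genes were higher in 4 of 13 (5), with the receptor Tek at 428 ± 289.9 against 4.3, and blood and microglial genes in 4 of 14 (4), with Laptm5 at 127 ± 19.7 against 4.5. Laptm5 was higher still in the iPS and ES cells (355.6 and 301.3), so it does not by itself mark blood cells here. The macrophage gene Lyz2 stood at 1434 on embryonic replicate 3 and at 11, 22.7 and 42.3 on the other 3 fibroblast-derived arrays, and the placental gene Tpbpa at 1006 ± 451 on the embryonic-derived and 1.75 ± 1.91 on the adult-derived pair. In these 4 lists the count in brackets was adjusted over the list alone.

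These 12 lists passed camera, with adjusted p between 1.1e-17 for the cell cycle and 0.0472 for the endothelial list. None held with an estimated correlation, where adjusted p was 0.191 for the neural stem cell, astrocyte and oligodendrocyte lists, 0.411 for the cell cycle, 0.579 for the keratinocyte and endothelial and 0.625 for the other 6. With the iPS or ES origin as a block, the endothelial and the blood and microglial lists no longer passed (adjusted p = 0.0556 for each), nor did the endothelial list without adult replicate 1 (0.0545) or the blood list without embryonic replicate 3 (0.11). In all, 3879 genes were called, 2132 higher and 1747 lower, with Mmd2 (-9.04 ± 0.38) and the neuronal membrane gene Gpm6a (-8.51 ± 0.82) among the lowest. With the adult fibroblast-derived arrays alone, Sox2 passed at a log2 difference of -3.79 and Nes turned to 0.40, and Sox2 also passed without adult replicate 1 (-1.57) or 2 (-3.14). The GE neurospheres were on 1 array, assumed to vary like the groups with 2.

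**Figure D2:**
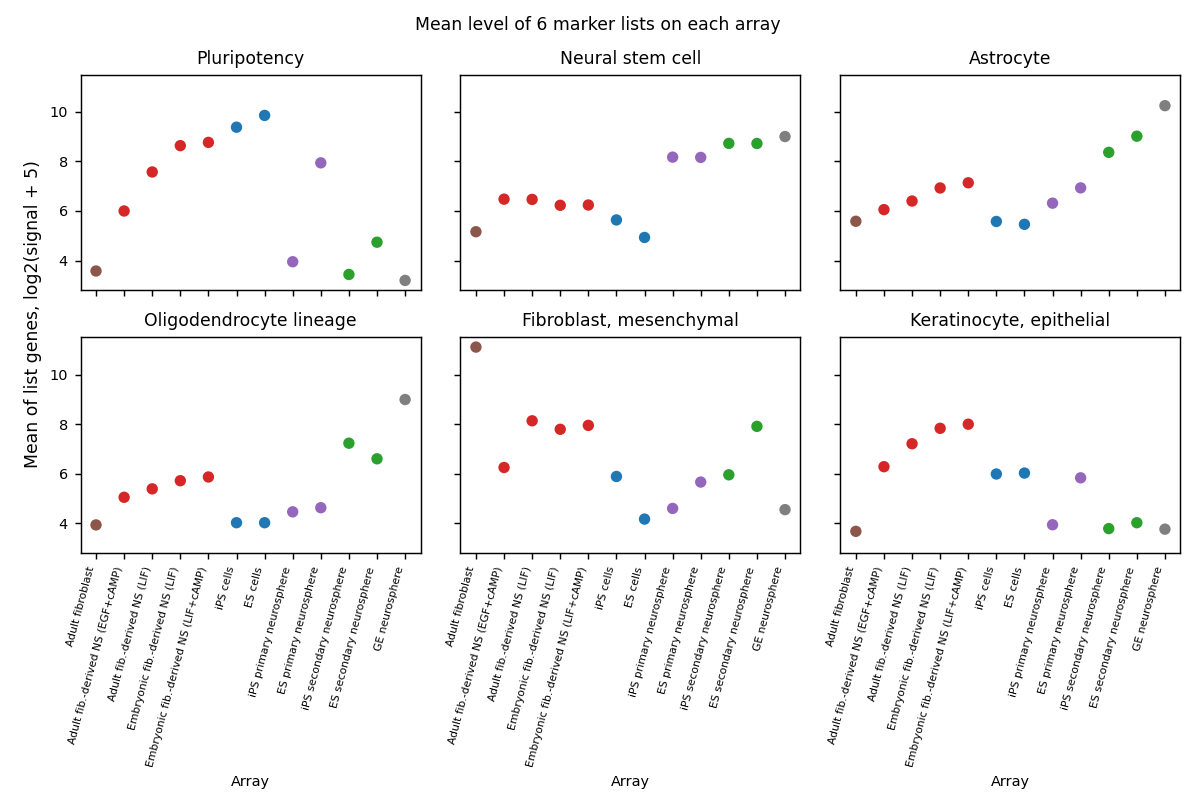
Mean of log2(signal + 5) over the measured genes of 6 marker lists, drawn for each of the 12 arrays as 1 point. Colours mark the groups: adult fibroblasts brown, fibroblast-derived neurospheres (NS) red, pluripotent cells blue, primary neurospheres purple, secondary neurospheres green and GE neurospheres grey. The 4 fibroblast-derived arrays lay below the other neurospheres in the neural stem cell list, where 19 of 29 genes were lower than in the GE neurospheres.

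Set against the iPS and ES cells, the fibroblast-derived neurospheres were compared for pluripotency genes. Pou5f1 stood at 2014 ± 180.0 (n = 4) against 2639.8 ± 251 (n = 2) and did not pass (log2 difference -0.39 ± 1.43, adjusted p = 0.858), and Nanog, at 961 ± 817 against 2584 ± 275, did not pass either (adjusted p = 0.354). The SE draws on every group with 2 arrays, also on primary neurospheres, where Pou5f1 stood at 9.6 and 1174.1. These missing calls therefore do not show equal levels. Nanog stood at 145.2 and 401.6 on the adult-derived arrays and at 1453.7 and 1844.9 on the embryonic-derived ones. Zfp42 (Rex1), a marker of naive pluripotency, was lower, at 226 ± 221 against 3678 ± 878 (log2 difference -5.05 ± 1.55, adjusted p = 0.0383). So was Esrrb, at 147 ± 118 against 812 ± 83.1. Higher were Fabp7, at 264 ± 236 against 9.05 ± 11.1, Ptprz1 at 315 ± 239.9 against 9.15 ± 1.2, Egfr at 194 ± 54.6 against 3.95 ± 0.354 and Nes at 127 ± 62.2 against 24.1 ± 22.4.

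Of 30 pluripotency genes 5 were lower and 0 higher (2 lower adjusted over the list alone). Of 29 cell cycle genes 23 were lower (24 adjusted over the list alone), with Top2a at -1.27 ± 0.18 and Mcm5 at -1.56 ± 0.26. Fibroblast genes were higher in 13 of 35 (18 adjusted over the list alone), including the collagen gene Col5a2, at 941 ± 729.7 against 27.4 ± 24, and the mesenchymal factor Prrx1. Adhesion genes were higher in 9 of 15 (9 adjusted over the list alone), with the hyaluronan receptor Cd44 at 2251 ± 474 against 28.6 ± 29.4 and Vim at 1.88 ± 0.12. The adjusted p in camera was 1.66e-05 for the pluripotency, 1.34e-11 for the cell cycle, 0.000242 for the fibroblast and 0.0178 for the adhesion list, and none of the 4 calls held with an estimated correlation (adjusted p = 0.713 for each). The neural stem cell list had 9 members higher and 2 lower of 29 (11 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.082, 0.0136 with a common median and 0.0126 without the iPS array). Without the ES array the mean difference of the fibroblast list was 1.64, over 1.5 times smaller. The lens and stress protein gene Cryab, at 3557 ± 1593 against 21.6 ± 8.77, and Sbspon, at 1512 ± 305 against 1.1 ± 1.41, were among the highest. The meiotic gene Ccnb1ip1 was among the lowest, at 5.03 ± 1.59 against 502 ± 198.

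Of 4126 genes called, 2790 were higher and 1336 lower. Without the ES array the count was 2099, without embryonic fibroblast-derived replicate 3 it was 2561 and without replicate 4 it was 2615. With a common median 35.6% of the calls were higher against 67.6% as deposited, the median of all genes moving by -0.44 (-0.21 under quantile normalization). Esrrb lost its call without the iPS (-2.81) or the ES array (-3.02). Zfp42 lost it with a smaller pseudocount, without a trend, and without the iPS (-5.29) or the ES array (-4.80), adult replicate 1 (-4.29) or embryonic replicate 3 (-4.94) or 4 (-5.16). Per the labels the strain is C57BL/6 except for the iPS and ES cells, so strain and origin cannot be told apart here. The primary and secondary neurospheres came from these lines, so the same limit holds for the comparison with the secondary neurospheres.

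**Figure D3:**
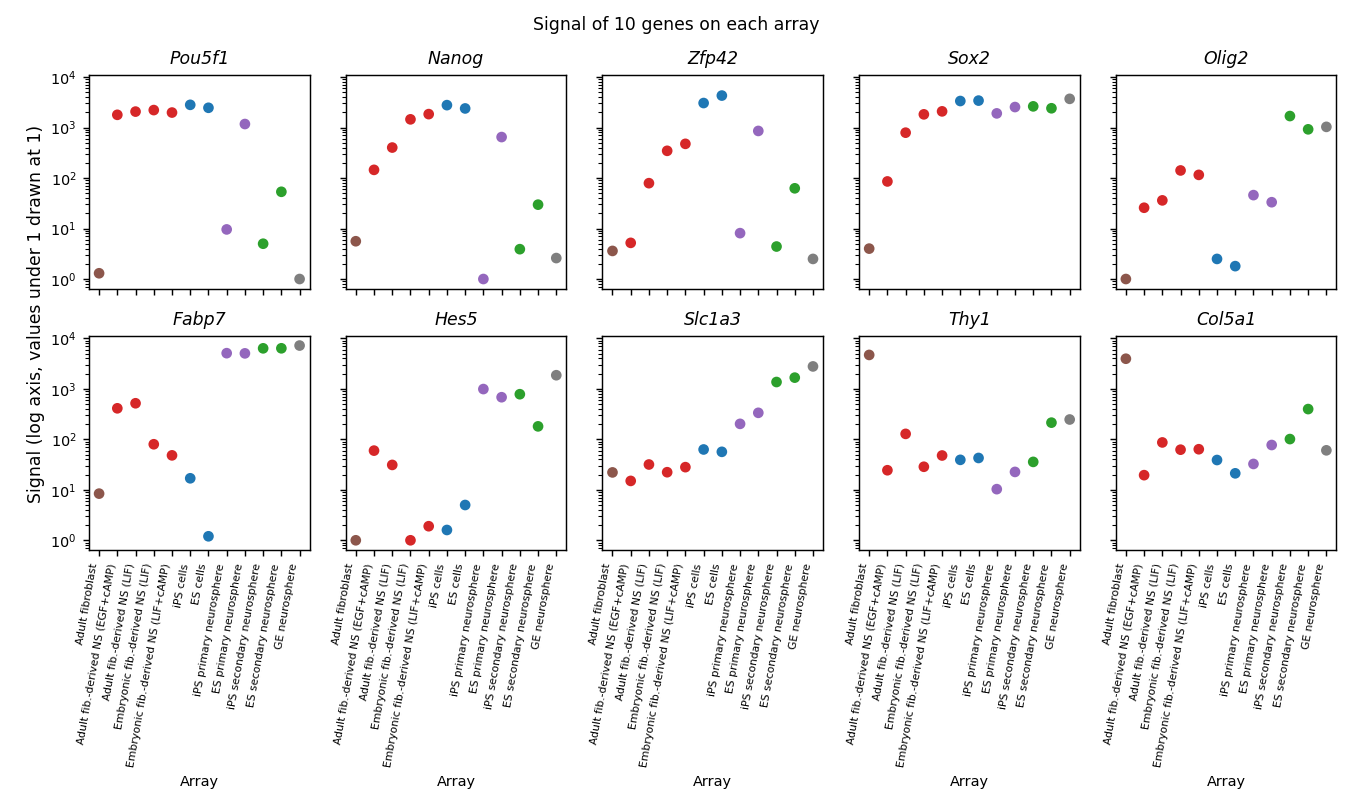
Signal of 10 genes on each of the 12 arrays, 1 point per array, on a log axis with signals under 1 drawn at 1. Colours mark the groups: adult fibroblasts brown, fibroblast-derived neurospheres (NS) red, pluripotent cells blue, primary neurospheres purple, secondary neurospheres green and GE neurospheres grey. Pou5f1 lay at 2014 ± 180.0 in the fibroblast-derived neurospheres (n = 4) and 2639.8 ± 251 in the pluripotent cells (n = 2), and Fabp7 lay at 264 ± 236 against 6343 ± 6.86 in the secondary neurospheres.

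The fibroblast-derived neurospheres were also compared with the secondary neurospheres of iPS and ES origin. The sonic hedgehog gene Shh stood at 12.5 ± 11.9 (n = 4) against 3469.8 ± 1048 (n = 2), a log2 difference of -7.82 ± 0.50 (adjusted p = 4.71e-05). On the GE array Shh stood at 13.6, so the low level was not particular to the fibroblast-derived neurospheres. Fabp7 was at 264 ± 236 against 6343 ± 6.86, Slc1a3 at 24.3 ± 7.3 against 1515 ± 213, and Olig2, a factor of oligodendrocyte and ventral progenitors, at 79.7 ± 57.4 against 1306 ± 542. Klk1, the mesothelial gene Msln, at 1333 ± 489 against 1.65 ± 0.919, and the epithelial galectin gene Lgals7 were higher. Pou5f1, at 2014 ± 180.0 against 29.2 ± 34.2, Sall4 and Fgf4 were also higher. Xist, the X-inactivation transcript of female cells, stood at 1918 ± 369.8 against 8.4 ± 0.707.

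The neural stem cell list had 18 of 29 members lower and 0 higher (22 adjusted over the list alone), including the Notch target Hey1 (-3.63 ± 0.28) and Cdh2 (-3.15 ± 0.26). Sox2, at 1199 ± 930.4 against 2518 ± 154, did not pass (adjusted p = 0.0696), and passed without adult replicate 1 (-1.01) or 2 (-2.58) and with the adult-derived arrays alone (-3.23). Astrocyte genes were lower in 12 of 19 (12), such as Sparcl1 (-6.98 ± 0.36) and Aldoc (-2.38 ± 0.19), with the count adjusted over the list alone in brackets here and for the lists that follow. Oligodendrocyte genes were lower in 10 and higher in 3 of 17 (10 and 4), with Gpr17 lower and Mal higher, and neuronal genes lower in 11 and higher in 2 of 24 (15 and 2), with Gap43, Dcx and Map2 lower. Imprinted genes were lower in 9 and higher in 1 of 22 (10 and 1), with Ndn at 304 ± 97.4 against 2985 ± 565 and Cdkn1c at 287 ± 173 against 1128 ± 332. Higher were 20 of 30 pluripotency genes (23), 15 of 17 keratinocyte genes (15 higher and 1 lower), 10 of 17 LIF response genes (10) with Socs3 at 3.48 ± 0.42 and Timp1 at 5.19 ± 0.49, and 9 of 16 hypoxia and glycolysis genes (14) with the hexokinase gene Hk2 at 839.7 ± 114 against 152 ± 47.2 and Ndrg1 at 355 ± 83.3 against 17.4 ± 5.73. The mean of the LIF response list was 6.94 on adult replicate 1, grown with EGF and cAMP, against 5.20 and 6.01 in the secondary neurospheres. On the fibroblast-derived arrays given LIF it was 7.97, 7.83 and 8.10. Also higher were 5 of 13 endothelial genes (5), 5 of 14 blood and microglial genes (5) with Laptm5 at 127 ± 19.7 against 6.75 ± 3.32, beside the Lyz2 and Tpbpa of the embryonic-derived arrays, 4 of 11 senescence and p53 genes (5) and 5 of 29 cell cycle genes (0). Laptm5 was higher still in the iPS and ES cells (355.6 and 301.3). The hypoxia mean was 6.77 and 7.03 in the secondary neurospheres, but 9.01 on the GE array, 8.83 in the fibroblasts and 7.90 and 8.11 in the iPS and ES cells. The imprinted mean was 7.39 and 7.97 in the secondary neurospheres, but 6.02 on the GE array and 6.41 in the fibroblasts. The fibroblast-derived arrays lay at 7.87 to 9.35 and 6.02 to 6.74, so the shifts in these lists also depend on the reference. The 13 lists passed camera with adjusted p between 1.34e-09 for the neural stem cell and 0.0186 for the endothelial list. With an estimated correlation none held: adjusted p was 0.179 for the neural stem cell list, 0.436 for 7 lists (astrocyte, oligodendrocyte, imprinted, keratinocyte, hypoxia, LIF response and endothelial), 0.529 for the neuronal, pluripotency and blood lists, 0.576 for the senescence and 0.651 for the cell cycle list. The fibroblast list, with 5 of 35 higher (4), did not pass (adjusted p = 0.37), and passed without secondary replicate 2 (0.00134). The cell cycle call was lost without secondary replicate 2 (adjusted p = 0.188), and the endothelial and blood calls without secondary replicate 1 (0.0529 and 0.0531).

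Of 4588 genes called, 2314 were higher and 2274 lower. Without secondary neurosphere replicate 1 (iPS) the count was 2450 and without replicate 2 (ES) it was 2431. Pou5f1 lost its call without the iPS array (5.11). Against the primary neurospheres instead, Pou5f1 (3.94), Sall4 (0.43) and Gpr17 (-0.48) did not pass, Aldoc turned to 1.35 and Olig2 to 0.64.

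The primary neurospheres were compared with the pluripotent cells they came from. Fabp7 went from 9.05 ± 11.1 to 5059 ± 31.4 (n = 2 on each side, log2 difference 8.76 ± 0.50, adjusted p = 0.000109), Dcx, a gene of young neurons, from 1.2 ± 0.849 to 1335 ± 811, the nuclear receptor gene Nr2f1 from 4.3 ± 1.27 to 1822 ± 616 and Hes5 from 3.3 ± 2.4 to 835 ± 217. Esrrb, of the pluripotency list, fell from 812 ± 83.1 to 68.5 ± 75.4 and Tfcp2l1 from 1044 ± 131 to 52.8 ± 70.3. Pou5f1, at 592 ± 823 against 2639.8 ± 251, did not pass (log2 difference -4.33 ± 1.66, adjusted p = 0.0787), and passed with the line as a block (adjusted p = 0.025). It stood at 9.6 in the iPS-derived and 1174 in the ES-derived primary neurospheres. Nanog, at 0.2 in the iPS-derived and 648 in the ES-derived, passed at 0.0485. Sox2 stood at 2227 ± 452 against 3385 ± 46 and did not pass.

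Of 29 neural stem cell genes 23 rose (23 adjusted over the list alone), including Nes (3.69 ± 0.49), Pax6 (3.03 ± 0.41) and Sox9 (4.21 ± 0.38), and of 24 neuronal genes 20 rose (22), including Map2 and the synaptic gene Snap25. In brackets here are the counts adjusted over the list alone. Midbrain, hindbrain and spinal patterning genes rose in 9 of 29 (9), with Hoxb3 at 779 ± 212 against 4.85 ± 0.636, Hoxb2 and Irx3. Adhesion genes rose in 7 of 15 (7, with 2 lower), including the neural adhesion genes Cdh2 (4.79 ± 0.31) and Ncam1 (3.82 ± 0.37) and Vim. Of 30 pluripotency genes 15 fell (25). Cell cycle genes fell in 18 of 29 (24), with Bub1b at -1.79 ± 0.31. LIF response genes fell in 8 of 17 (10), with Socs3 at -3.75 ± 0.49, Bcl3 and Klf4, and keratinocyte genes in 3 of 17 (3), with Krt17 at -2.79 ± 0.45. These 8 lists passed camera with adjusted p between 1.59e-09 for the neural stem cell and neuronal and 0.0485 for the keratinocyte list. None held with an estimated correlation, where adjusted p was 0.195 for the neural stem cell, 0.565 for the keratinocyte and 0.543 for the other 6 lists. The keratinocyte call was also lost with a common median (adjusted p = 0.103) and without the iPS (0.0519) or the ES cells (0.0749), and the patterning call without the ES cells (0.0568). Without the iPS-derived primary neurospheres the mean difference of the pluripotency list was -1.67 against -3.67, that of the cell cycle list -0.68 against -1.01 and that of the keratinocyte list, no longer called, -0.17 against -1.12. Without the ES-derived ones the pluripotency list stood at -5.66 and the keratinocyte list at -2.06. The fibroblast list, with 1 of 35 lower (1), did not pass (adjusted p = 0.674), and its median (-0.0067) and mean (0.10) differed in sign.

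Of 4107 genes called, 2631 rose and 1476 fell. The count was 1558 without the iPS-derived primary neurospheres, 2605 without the ES cells and 1387 with only the 4 arrays compared in the fit. With a common median 39.4% of the calls were higher against 64.1% as deposited, the median of all genes moving by -0.35 (-0.14 under quantile normalization). Nanog lost its call without the iPS-derived primary neurospheres (-1.98), the iPS (-5.36) or the ES cells (-5.58), and under quantile normalization, a smaller pseudocount, no signal filter, the mean of probe sets, no trend and the fit of 4 arrays. Pou5f1 passed without the ES-derived primary neurospheres, at a log2 difference of -7.50.

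Secondary neurospheres were compared with primary ones. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, went from 81.1 ± 22.1 to 3539 ± 405 (n = 2 on each side, log2 difference 5.38 ± 0.49, adjusted p = 0.005) and from 39.5 ± 8.98 to 1306 ± 542. The astrocytic genes Aldoc and Sparcl1 rose to 3004 ± 165 and 3511 ± 596 from 226 ± 53.3 and 412 ± 15. The retinoic acid-binding protein genes Crabp1 and Crabp2 fell, Crabp2 from 1752 ± 791 to 23.9 ± 30.1 (log2 difference -6.42 ± 0.75, adjusted p = 0.00805). Neurog2, which drives neuronal differentiation, fell from 197 ± 86.9 to 5.45 ± 6.58.

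Of 17 oligodendrocyte genes 9 rose (12 adjusted over the list alone, as for each bracket that follows), including Mbp (4.60 ± 0.55) and Gpr17 (4.15 ± 0.44), and of 19 astrocyte genes 9 rose (11), including Aldoc (3.72 ± 0.21). EGF, FGF and MAPK response genes rose in 3 of 17 (5). Neuronal genes fell in 6 of 24 (14), including Nefl (-3.76 ± 0.70), and pluripotency genes in 2 of 30 (3). No single member passed in the fibroblast (0 of 35), cAMP and CREB response (3 of 20 adjusted over the list alone) and cell cycle (0 of 29) lists, although the first 2 shifted up and the last down in camera. The 8 list calls had adjusted p between 2.71e-11 for the astrocyte and 0.0211 for the cAMP list. None held with an estimated correlation: adjusted p was 0.195 for the oligodendrocyte and astrocyte, 0.577 for the neuronal, 0.741 for the EGF and 0.801 for the other 4 lists. Without the ES-derived primary neurospheres the mean difference of the pluripotency list turned from -1.86 to 0.14, and the cell cycle (-0.20 against -0.54) and cAMP (adjusted p = 0.118) calls were lost, while the EGF list stood at 1.46 against 0.97. Without the iPS-derived ones the pluripotency list stood at -3.85, the cell cycle list at -0.87 and the EGF list at 0.49. Without the iPS-derived secondary neurospheres the pluripotency list stood at -1.21 and the fibroblast list at 2.78 against 1.80, and without the ES-derived ones the fibroblast list stood at 0.82 and the cell cycle list at -0.28. The neural stem cell list had 4 members higher and 1 lower of 29 (8 and 2) and did not pass (adjusted p = 0.195). The receptor gene Egfr, at 704 ± 42.7 against 35.8 ± 25.7, was among those higher, and Pax6, at a log2 difference of -2.80 ± 0.41, was the one lower.

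Of 380 genes called, 272 were higher and 108 lower, and with the line (iPS or ES) as a block 648 were called, 414 higher and 234 lower. The count was 36 without secondary replicate 2 (ES), 133 without secondary replicate 1 (iPS), 236 without primary replicate 1 (iPS), 190 or 604 with a smaller or larger pseudocount and 2 with only the 4 arrays compared in the fit. In that last fit Olig1 and Crabp1 passed and the other genes named for this comparison did not. Crabp1 lost its call without secondary replicate 1 (-5.08) or 2 (-4.74), Neurog2 without secondary replicate 2 (-3.67), Sparcl1 without it (2.89) or with a smaller pseudocount, Nefl without primary replicate 1 (-3.13) or secondary replicate 2 (-2.91), and Pax6 without primary replicate 1 (-2.53) or secondary replicate 1 (-2.97) or 2 (-2.62).

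Adult and embryonic fibroblast-derived neurospheres were compared for the age of the donor cells, with media that were not matched. Tpbpa, a marker of trophoblast, stood at 1.75 ± 1.91 in the adult-derived and 1006 ± 451 in the embryonic-derived neurospheres (n = 2 each, log2 difference -7.18 ± 0.44, adjusted p = 0.000378). The placental cathepsin gene Ctsj was at 0.5 ± 0.424 against 822 ± 440.0, and the placental prolactin-family genes Prl2a1 at 7.85 ± 0.354 against 1069.6 ± 509, Prl7d1 at 1.9 ± 0.566 against 439 ± 347, Prl7b1 at 6.7 ± 1.27 against 543 ± 120.1 and Prl4a1 at 2.05 ± 0.636 against 211 ± 60.7. These families have near-identical members, so which member was measured is uncertain. The peptide hormone gene Iapp was higher in the adult-derived, at 182 ± 112 against 1.45 ± 0.778, and so was Cdh2, at 415 ± 38.5 against 98 ± 45.

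The macrophage gene Cd68 was lower in the adult-derived neurospheres, at 33.3 ± 11.5 against 177 ± 38.7. Sox2 (438 ± 499 against 1959 ± 188), Nanog (273 ± 181 against 1649 ± 277), Klf4 and Olig2 did not pass (adjusted p = 0.201, 0.611, 0.205 and 0.0727). Neither did Fabp7, at 464 ± 75.2 against 64 ± 22.4 (adjusted p = 0.0677), Hoxc4, at 180.5 ± 114 against 1.6 ± 0.849 (adjusted p = 0.129, and 0.0375 with the iPS or ES origin as a block), or Hoxa10, at 26.7 ± 5.8 against 301 ± 19.9. That block acts on the arrays of iPS and ES origin and on no fibroblast-derived array. Here it changes only the spread pooled over groups. Camera called 12 lists, each with at most 1 member called over all genes. The pluripotency, fibroblast, keratinocyte, hypoxia, cAMP response, oligodendrocyte, endothelial, blood and microglial, astrocyte and reprogramming factor lists shifted down and the cell cycle and the midbrain, hindbrain and spinal patterning lists up. Adjusted over the list alone, 7 of 13 endothelial genes were lower and 1 higher, 10 of 29 patterning genes higher and 3 lower, and 4 of 14 blood and microglial genes lower. The counts lower were 3 of 19 for the astrocyte, 2 of 16 for the hypoxia, 2 of 17 for the oligodendrocyte, 2 of 4 for the reprogramming factor and 0 for the pluripotency, fibroblast, keratinocyte and cAMP lists, and the cell cycle list had 0 higher. Adjusted p in camera lay between 2.54e-06 for the pluripotency and 0.0465 for the fibroblast list. None held with an estimated correlation, with adjusted p of 0.511 for the pluripotency, 0.665 for the cell cycle, 0.772 for the fibroblast and 0.436 for the other 9 lists. Several shifts rested on 1 array. Without adult replicate 1, grown with EGF and cAMP, the mean difference of the fibroblast list turned from -0.68 to 0.26, and those of the pluripotency (-1.13 against -1.91), keratinocyte (-0.70 against -1.17) and reprogramming factor lists (-0.95 against -1.52) were smaller. The fibroblast list stood at -1.62 without adult replicate 2, and its call was lost without embryonic replicate 3 (adjusted p = 0.0607) or 4 (0.0986). Without embryonic replicate 3, the array with high Lyz2, the blood and microglial list stood at -0.69 against -1.46, and without replicate 4 at -2.23. The oligodendrocyte call was lost without adult replicate 1 (adjusted p = 0.0555), the endothelial without adult replicate 2 (0.0532) and the cAMP call without embryonic replicate 4 (0.13). The neural stem cell list, with Cdh2 the one member called (4 higher and 3 lower adjusted over the list alone), did not pass (adjusted p = 0.111).

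Of 64 genes called, 9 were higher in the adult-derived and 55 in the embryonic-derived neurospheres, and 29 were called with the iPS or ES origin as a block. The count was 13 without adult replicate 1, 10 without embryonic replicate 3, 11 without embryonic replicate 4, 41 under quantile normalization, 9 or 139 with a smaller or larger pseudocount, 10 with a stricter signal filter and 15 with only the 4 arrays compared in the fit. Tpbpa, Ctsj, Prl2a1, Prl7b1 and Prl4a1 passed in each of these. Prl7d1 lost its call without adult replicate 1 (-5.83, adjusted p = 0.0715), with the smaller pseudocount (adjusted p = 0.0816) and with only the 4 arrays in the fit (adjusted p = 0.0693). Iapp lost its call without adult replicate 2 (4.08) or embryonic replicate 3 (4.85) or 4 (4.60), Cdh2 without adult replicate 1 (2.19) or 2 (2.0) or embryonic replicate 4 (1.64), and Cd68 without any 1 of the 4 arrays (-1.96, -2.58, -2.49 and -2.05). Iapp, Cdh2 and Cd68 also lost it with the stricter filter (adjusted p = 0.0768, 0.0768 and 0.114), the smaller pseudocount (0.0806, 0.0835 and 0.137) and the fit of 4 arrays (0.0678, 0.106 and 0.0937). Cd68 lost it without a filter (adjusted p = 0.0534), and under the block Cdh2 (adjusted p = 0.0517) and Cd68 (adjusted p = 0.0534) did not pass. Sox2 passed without adult replicate 2 (-4.43).

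**Figure D4:**
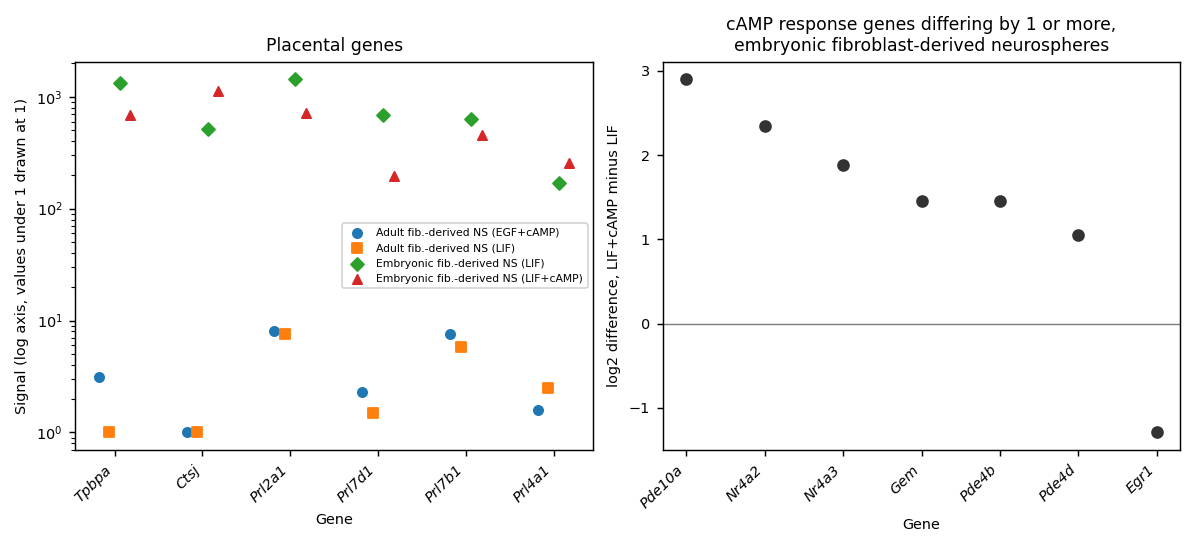
The left panel gives the signal of 6 placental genes on the 4 fibroblast-derived neurosphere (NS) arrays, 1 point per array, on a log axis with signals under 1 drawn at 1. The right panel gives the log2 difference between the embryonic fibroblast-derived arrays with and without cAMP for the 7 cAMP response genes that differed by 1 or more. Tpbpa lay at 1.75 ± 1.91 in the adult-derived and 1006 ± 451 in the embryonic-derived neurospheres (n = 2 each).

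Origin from iPS or ES cells was tested over the pluripotent cells and both kinds of neurosphere, with the stage as a term (3 arrays on each side). The one gene called was Eif2s3y, a gene of the Y chromosome, at 2.6 ± 1.97 in iPS and 465 ± 177 in ES origin (log2 difference -5.92 ± 0.30, adjusted p = 0.0136). Uty, also on the Y chromosome, stood at 3.23 ± 1.06 against 134 ± 50.3 and did not pass (adjusted p = 0.0676), and Xist was at 21.3 ± 17.7 against 24.8 ± 22.8 (log2 difference -0.11 ± 0.30, and 0.055 with the mean of probe sets). Dnmt3l and Fbxo15, genes of pluripotent and germ cells, stood at 87.3 ± 143 against 845 ± 1234 and 164 ± 272 against 788 ± 1138 and did not pass (adjusted p = 0.245 for each). Camera called 7 lists. The pluripotency list shifted down in iPS origin, with 0 of 30 members called over all genes and 15 lower adjusted over the list alone, and the neuronal list shifted up, with 0 of 24 called by either adjustment. The sex chromosome (1 of 4 lower, 2 adjusted over the list alone), astrocyte (0 of 19, 2), hypoxia (0 of 16, 0), keratinocyte (0 of 17, 0) and skeletal muscle lists (0 of 8, 0) shifted down. Adjusted p in camera lay between 3.56e-15 for the pluripotency and 0.0419 for the astrocyte list, and each was 0.76 with an estimated correlation. The neural stem cell and fibroblast lists, with no member called by either adjustment, did not pass (adjusted p = 0.101 and 0.0688). The neural stem cell list passed without either secondary array (adjusted p = 0.0467 and 0.0469), and the fibroblast list without either pluripotent array (3.43e-14 and 1.54e-14). The list shifts differed between stages. The iPS minus ES difference of the pluripotency list was largest in the primary neurospheres, and without either primary array its mean was -0.89 against -1.92. There the hypoxia (-0.24 against -0.53) and neuronal lists (0.42 against 0.65) were also smaller, and the keratinocyte (-0.14 against -0.72) and skeletal muscle calls (-0.20 against -0.73) were lost. Without either secondary array the astrocyte call was lost (-0.25 against -0.38). Without either pluripotent array the astrocyte, neuronal and skeletal muscle lists stood at -0.63, 1.05 and -1.12. Limma called 1 gene with 1628 at an unadjusted p under 0.05, 0 without either pluripotent array or the ES-derived primary neurospheres, 3 without the iPS-derived and 2 without the ES-derived secondary neurospheres, and 0 without the stage term. Eif2s3y stood at -5.80 without either pluripotent array and -5.79 without the ES-derived primary neurospheres, where it did not pass. The skeletal muscle call was lost under quantile normalization (adjusted p = 0.0563). Each origin was 1 line, so line and origin cannot be told apart.

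Media were compared within each donor age on 1 array each, so these are values without a replicate or a test. Adding cAMP to LIF in the embryonic-derived neurospheres went with 297 genes higher and 265 lower by 1 or more on the log2 scale. The cAMP and CREB response list had a median difference of 0.67, at percentile 100 of 10000 random lists matched on level. Of the 24 lists, 8 lay outside the central 95% of their random lists in this pair and 16 in the adult-derived pair, so such percentiles are common between single arrays. Of the 20 genes of the cAMP list, 6 were higher by 1 or more, the phosphodiesterase genes Pde10a (79.2 against 6.3), Pde4b and Pde4d, the nuclear receptor genes Nr4a2 (228.5 against 41.1) and Nr4a3, and Gem. Egr1 was lower, at 563 against 1385. The blood and microglial list had a median of -1.71 (percentile 0) with 9 of 14 lower, and the lowest among genes at 100 or more on 1 of the arrays were the macrophage genes Lyz1 (31.3 against 2137), Marco (0.5 against 194) and Lyz2 (42.3 against 1434), followed by Clec4d and Cybb. The highest were Gbp2, at 614 against 30.7, Mcpt8, Pi15, Iigp1 and Il6. Lcn2 was the one LIF response gene that differed by 1 or more, at 938 against 182, and in the EGF response list, with a median of -0.23 (percentile 0.18), Fosl1 and Ier3 were higher and Egr1 lower.

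In the adult-derived neurospheres, the array with EGF and cAMP had 389 genes higher and 1084 lower than the array with LIF. The fibroblast list had a median of -1.85 (percentile 0), with 25 of 35 lower, and Col1a2 was at 39.5 against 1449 and Postn at 8.2 against 641. The pluripotency list had a median of -1.51 (percentile 0), with 21 of 30 lower and 1 higher. In the LIF response list, with a median of -0.77 (percentile 0.01), 7 of 17 genes were lower: Lcn2 (8.9 against 299), Cp, Serpina3n, Tfcp2l1, Osmr, Klf4 and Fos. The cAMP list had a median of 0.018 (percentile 59.4), with Atf3, Bdnf, Dusp1 and Fos lower by 1 or more, and in the EGF response list, with a median of -0.22 (percentile 1.86), Fosl1 was higher and Dusp4 and Il17rd lower. The hypoxia and the imprinted gene lists had medians of -0.59 and -0.65 (percentile 0 for both). The acute-phase gene Saa3 (38.8 against 2345), the protease gene Mmp3 (31.4 against 1436) and Ms4a4d were also among the lowest. Erdr1 (1339 against 23.5), Akr1c18, Ces1f, Notch4 and Slc2a6 were the highest.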

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

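The tests of pluripotent cells mixed into the fibroblast-derived cultures, of other placental markers without a signal filter, of culture additives and of array scaling were chosen only after the results were seen.

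Among 3804 probe sets without a single gene symbol, which enter no comparison of genes, 519 were higher and 145 lower in the fibroblast-derived neurospheres than in the adult fibroblasts. That is 17.5% called, against 21.0% of all 28345 probe sets (5960).

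Pluripotency genes were high in the fibroblast-derived neurospheres, with a median difference from the fibroblasts of 3.91 or above under both other scalings (4.13 as deposited), which argues against array scaling. Mixed-in pluripotent cells like the 2 lines would bring every abundant transcript at 1 common share. Pou5f1 had shares of 67.9% and 78.6% on the adult-derived arrays. On both arrays, 7 of 133 other genes abundant in both lines lay over 10 times below that level, among them Zfp42 at 5.2 and 79.1 against 3678. That argues against cells like these lines as the whole source of Pou5f1 there. The count was 0 in the ES-derived primary neurospheres, which came from 1 of the 2 lines. That 0 therefore does not show how pluripotent cells of another strain would score. Ccnb1ip1, at 3.2 and 4.2 against 502 on the adult-derived arrays, is 1 of the 7 and may differ between strains. For the other 23 list members on these arrays the SD of the log2 shares was 1.62 and 1.09, against 1.16 between the lines, so a mixture and expression in the cells cannot be told apart, because 1 of the 2 arrays was above that spread and Zfp42 alone lay over 10 times below the median shares of 5.82% and 25.5% on both. On the embryonic-derived arrays the lower SD over 24 members was 0.687, under the 1.14 between the lines, and here too the 2 cannot be told apart, because Ccnb1ip1 alone, at 6.5 and 6.2 against 502, lay over 10 times below the median shares of 53.1% and 56.8%, and 1 gene, which may differ between strains, decides nothing. The labels name no transgene, endogenous and introduced Pou5f1 transcripts were not told apart here, and no biological explanation was tested.

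Placental genes were high in the embryonic fibroblast-derived neurospheres. Between the arrays given LIF alone, the median difference of Tpbpa, Ctsj, Prl2a1, Prl7d1, Prl7b1 and Prl4a1 was 6.60 (4.53 to 7.94), which argues against the additives, and it stayed at 5.91 or above under other scalings (6.02 as deposited). The 43 other placental markers with a probe set, of 59 listed and without a signal filter, had a median difference of 0.52, at percentile 100 of 10000 random lists matched on level, with 16 higher and 1 lower by 1 or more. Some of the 16, such as Prl6a1, Prl7c1, Ctsr and Tpbpb, are of the same families as the genes named above. They are not independent of those genes, so random lists of unrelated genes are not a fair yardstick for them. Of the 49 markers with a probe set, 1 reached 200 on both pluripotent arrays and 2 on at least 1 of them, and 3 are in other lists. Trophoblast cells in the cultures are a candidate source, and the age of the donor stays open as untested.

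Pluripotency genes were also high in the ES-derived primary neurospheres. Scaling left their median difference from the iPS-derived ones at 3.80 or above (3.92 as deposited), which argues against it. If undifferentiated ES cells remained, other ES-high genes should keep a like share of their ES level. The median share was 22.4% over 101 such genes and 20.02% over 23 list members, all chosen to lie at or under 0.1 times the ES level in the iPS-derived primary, both secondary and the GE neurospheres. Leftover ES cells may therefore account for the pattern, while a difference between the lines stays open as untested.

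The call of Eif2s3y between iPS and ES origin was set against the 10 splits of the 6 arrays. The real split called 1 gene and the highest other 0, so 1 of 10 splits called as many, and 10 splits are too few for a share under 0.05. Some of the other splits did not keep the stages balanced over the sides, so fewer than 10 are fair regroupings.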

How the results depend on the processing

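The use of the adult-derived arrays alone against the GE neurospheres, pluripotent cells and secondary neurospheres (3209, 2926 and 3168 genes), and the rescaling and left-out arrays for gene lists, were chosen after seeing the data. The order of the mean correlations was the same under every setting run, none of which left out an array. Of 142 called genes named, the call was lost in 1 under quantile normalization, 0 with a common median, 7 and 0 with the smaller and larger pseudocount, 2 without a filter, 15 of 141 with only the groups compared and in 34 of 654 fits that left out an array, and none of these turned its sign. Where a setting moved a value the cause was not tested, except that every probe set on its own tests more features and a left-out array leaves fewer. Arrays of 1 per group and dim signals limit what can be called.

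With every probe set on its own the counts were 5960, 6820, 7299, 8403, 7425, 998, 99 and 19 in the order reported. Leaving out 1 array gave 2010 to 2581 genes against the adult fibroblasts, 2868 to 3441 against the GE neurospheres, 2099 to 3894 against the pluripotent cells and 2431 to 3755 against the secondary neurospheres. It gave 1558 to 4535 for primary neurospheres against pluripotent cells, 36 to 259 for secondary against primary, 10 to 49 for adult against embryonic and 0 to 3 for iPS against ES origin. With only the groups compared, the counts were 1387 for primary against pluripotent, 2 for secondary against primary and 15 for adult against embryonic. For secondary against primary neurospheres, pseudocounts of 0.01 and 0.2 gave 190 and 604, and the replicate block of iPS or ES origin gave 648. For adult against embryonic, quantile normalization gave 41, the same pseudocounts 9 and 139, the filter at the trimmed mean 10 and the block 29. Between iPS and ES origin a common median gave 3 genes and the fit without the stage term, and so without its block, 0. Besides the calls given with the results, the block changed no other call of a named gene or list.

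Camera with an estimated correlation called 0 lists in each of the 8 comparisons. Fry called 6 against the GE neurospheres, 8 against the pluripotent cells, 2 for secondary against primary, 0 for adult against embryonic and 0 for iPS against ES origin, and a common median gave 11 against the pluripotent cells. Leaving out 1 array gave 6 to 8 lists against the adult fibroblasts, 11 to 12 against the GE neurospheres, 4 to 8 against the pluripotent cells, 13 to 14 against the secondary neurospheres, 7 to 12 for primary against pluripotent, 6 to 12 for secondary against primary, 11 to 12 for adult against embryonic and 7 to 15 for iPS against ES origin. The fibroblast list between primary neurospheres and pluripotent cells, which was not called, turned its direction with fry (adjusted p = 0.963), with a common median (adjusted p = 0.694) and without the iPS cells or the iPS-derived primary neurospheres (0.0771 to 0.693 over the left-out arrays). It also turned without the iPS-derived secondary neurospheres against these (0.00134 to 0.982), without either secondary array between origins (1.54e-14 to 0.426) and without adult replicate 1 for adult against embryonic (2.2e-05 to 0.408). The pluripotency list turned for secondary against primary without the ES-derived primary neurospheres (1.75e-20 to 0.836). For these turned lists, each range in brackets spans the adjusted p of all fits that left out 1 array. It includes fits that kept their direction, so its lower end does not show that a turned shift passed. Xist turned to 0.055 between iPS and ES origin with the mean of probe sets, Nes to 0.40 against the GE neurospheres with the adult-derived arrays alone, and Aldoc to 1.35 and Olig2 to 0.64 with the primary neurospheres as reference.

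The mean r with the adult fibroblasts was 0.777 and 0.806 with the smaller and larger pseudocount and 0.865 without a filter, and with the pluripotent cells 0.824, 0.854 and 0.890, and 0.836 as Spearman's rho. Without a filter it was 0.820 with the GE, 0.856 with the primary and 0.85 with the secondary neurospheres.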

Other observations

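Transcripts of the sex chromosomes differed between the cultures. Xist stood at 2708 in the GE neurospheres, 825 in the adult fibroblasts, 2342 and 2111 in the adult-derived and 1640 and 1578 in the embryonic-derived neurospheres. Eif2s3y, of the Y chromosome, stood at 666, 396 and 332 on the ES-origin arrays and at 146 and 131 on the embryonic-derived arrays, which therefore held both transcripts. These are values of single arrays without a test.

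In the adult-derived neurospheres, the midbrain, hindbrain and spinal patterning list had a median difference of 0.38 between EGF with cAMP and LIF, at percentile 99.95, with 9 of 29 genes higher by 1 or more. The keratinocyte list had a median of -0.86 (percentile 0.02), with 7 of 17 lower. In the embryonic-derived neurospheres, adding cAMP to LIF went with a median of 0.25 in the LIF response list (percentile 99.7).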
